A study of Mus musculus with 12 samples.

How the data were processed

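RNA of sorted mouse leukemia cells (7 µg of total RNA per array, isolated with Trizol and converted to biotin-labelled cRNA, per the labels' protocols) was measured on 12 Affymetrix arrays. They form 4 groups of 3: control and Rictor-deleted MLL-AF9 leukemia, and control and Rictor-deleted MLL-NRIP3 leukemia. Groups and replicate numbers were taken from the sample titles. The deposited values are linear intensities, 1 per probe set and array. How the authors summarised probes, corrected the background and normalized the arrays is not given in the sources used here. The 6 arrays of each model share nearly 1 distribution of values that differs from that of the other model, so the 2 sets look as if they were normalized separately. Levels set across the models are therefore not on 1 scale.

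The table holds 45101 probe sets with no missing value. By the platform annotation, 34958 had 1 gene symbol, 932 had several and 9211 had none, and genes were named only from probe sets with 1 symbol. This gave 18195 genes, of which 18033 were found by Entrez number in a RefSeq table of assembly GRCm38.p6, used only for chromosomes and neighbouring genes. Each gene was represented by its brightest probe set over the 12 arrays. Among the genes called, 78 in MLL-AF9 leukemia had a further probe set, of which 66 had the same sign and 0 were called in the opposite direction; in MLL-NRIP3 leukemia these numbers were 883, 674 and 13. The 5613 genes with a mean intensity under 7.58, the 40th percentile of all probe sets, were left out, and 12582 were tested.

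Intensities were used as log2(intensity + 16). One model with a mean for each of the 4 groups was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend, 8 residual degrees of freedom). Tests were 2-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. The contrasts were deleted against control in each model, the difference of these responses (MLL-NRIP3 minus MLL-AF9), their average, and MLL-NRIP3 against MLL-AF9 controls. Standard errors are those of the moderated fit. An exact permutation test of 3 against 3 arrays cannot give a p under 0.1 and was not used. Overlaps of calls were tested with Fisher's exact test. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

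The design, the thresholds, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule took, per contrast, the 10 largest increases and the 10 largest decreases among genes called whose 3 values in one group all lay above the 3 of the other, and left out clone names and predicted genes. The condition on separate values was not applied to the difference and the average, which involve 4 groups. Rictor, Kit, Ptprc and the sex-linked genes were always given, as were up to 4 members with the smallest p of each list described. Ly6g and Ddx3y were also to be given but had no probe set of their own used here; Eif2s3y, chosen after its values were seen, stands in for Ddx3y. Genes named beyond this rule (the shared calls, Trem3, Olfm4 among them, and Fcnb) were chosen after their values were seen.

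Gene lists of cell types, pathways and complexes were tested with camera (preset correlation between genes 0.01), adjusted over 35 lists, with camera with an estimated correlation and the self-contained test fry beside it. Camera compares a list with the other genes, whereas fry asks whether its members move, on balance, one way. With an estimated correlation the mature neutrophil list kept its call in MLL-AF9 leukemia, and no other list did in any contrast.

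The fit was tested on simulated data with the replicate spread of each model and 200 changed genes among 12582. With all arrays, 58%, 96%, 96% and 100% of genes with log2 changes of 0.5, 1, 2 and 3 were recovered in MLL-AF9 leukemia, and 62%, 94%, 98% and 100% in MLL-NRIP3 leukemia. False calls made up 1.69% of 178 calls and 40.4% of 297 calls. With the arrays of the model alone, the recovered shares were 80%, 100%, 100% and 100% in MLL-AF9 leukemia and 26%, 66%, 98% and 98% in MLL-NRIP3 leukemia, with false shares of 2.56% and 2.70%. The shared estimate of the spread was kept as designed, and counts from each model's own arrays are given beside it.

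Alternatives were quantile normalization, median centring, other filters and pseudocounts, the mean of a gene's probe sets, each probe set on its own, each model's own arrays, other forms of moderation, array weights, an unmoderated test, other thresholds, a replicate block, and leaving out each array in turn. After the data were examined, the omission of MLL-NRIP3 control arrays 1 and 2, the signal of 14 hybridization control probe sets as a covariate, the omission of genes on the sex chromosomes, and group means in place of every array for genes at the floor in one genotype were added.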

Results

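Gene expression was measured in leukemia cells sorted from the bone marrow of mice, with and without Rictor, an essential component of the kinase complex mTORC2. The leukemias were driven by either of 2 fusions of the MLL gene, MLL-AF9 or MLL-NRIP3. For each fusion, 3 arrays came from controls and 3 from Rictor-deleted leukemia, 12 arrays in all. Cells labelled K+G– were sorted after the first bone marrow transplantation, once CD45.2+ cells exceeded 50% of the white blood cells in peripheral blood. The labels call the cells bone marrow cells and give peripheral blood as the host tissue. The series text gives the aim as finding the molecular events that follow loss of Rictor in MLL-AF9 leukemia, with MLL-NRIP3 leukemia for further examination. Nothing in the labels says whether the 3 arrays of a group came from separate mice, so p-values measure only the spread between these arrays. The median intensity lay between 8.16 and 8.36 on the MLL-AF9 arrays and between 13.6 and 14.2 on the MLL-NRIP3 arrays, and the number of arrays limits the precision. Fold changes below are on the scale of log2(intensity + 16) and understate the changes of dim genes. Of 18195 genes with a probe set of their own, 12582 were tested.

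The Rictor probe sets did not show a clear loss of transcript. The brightest, 1435698_at, read 86.8 ± 4.80 (SD, n = 3) in MLL-AF9 controls and 87.5 ± 9.26 (SD, n = 3) in Rictor-deleted leukemia. In MLL-NRIP3 leukemia it read 113 ± 26.0 in controls and 104 ± 18.6 in Rictor-deleted cells (SD, n = 3 each). Probe set 1441753_at was 21.9 ± 1.13 in MLL-AF9 controls against 16.5 ± 2.52 in deleted cells, and 1429810_at was 30.9 ± 1.84 against 25.3 ± 1.10, with adjusted p of 0.89 and 1 in limma. Their unadjusted p was 0.060 and 0.18, or 0.012 and 0.025 when the 6 MLL-AF9 arrays were fitted alone. Probe set 1453775_at rose in MLL-NRIP3 leukemia from 49.7 ± 14.8 to 113 ± 44.8 (SD, n = 3 each, limma adjusted p = 0.028), a call that ended without control array 1 or 2 or Rictor-deleted array 1 or 2 (adjusted p from 0.077 to 0.12) and with the model's own arrays (0.23). Probe set 1427583_at stayed near 4 on average in all 4 groups. The part of Rictor that was deleted and the positions of these probe sets are not given in the sources used here. A probe set outside the deleted part need not fall, so these values do not check the genotype labels.

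**Figure D1:**
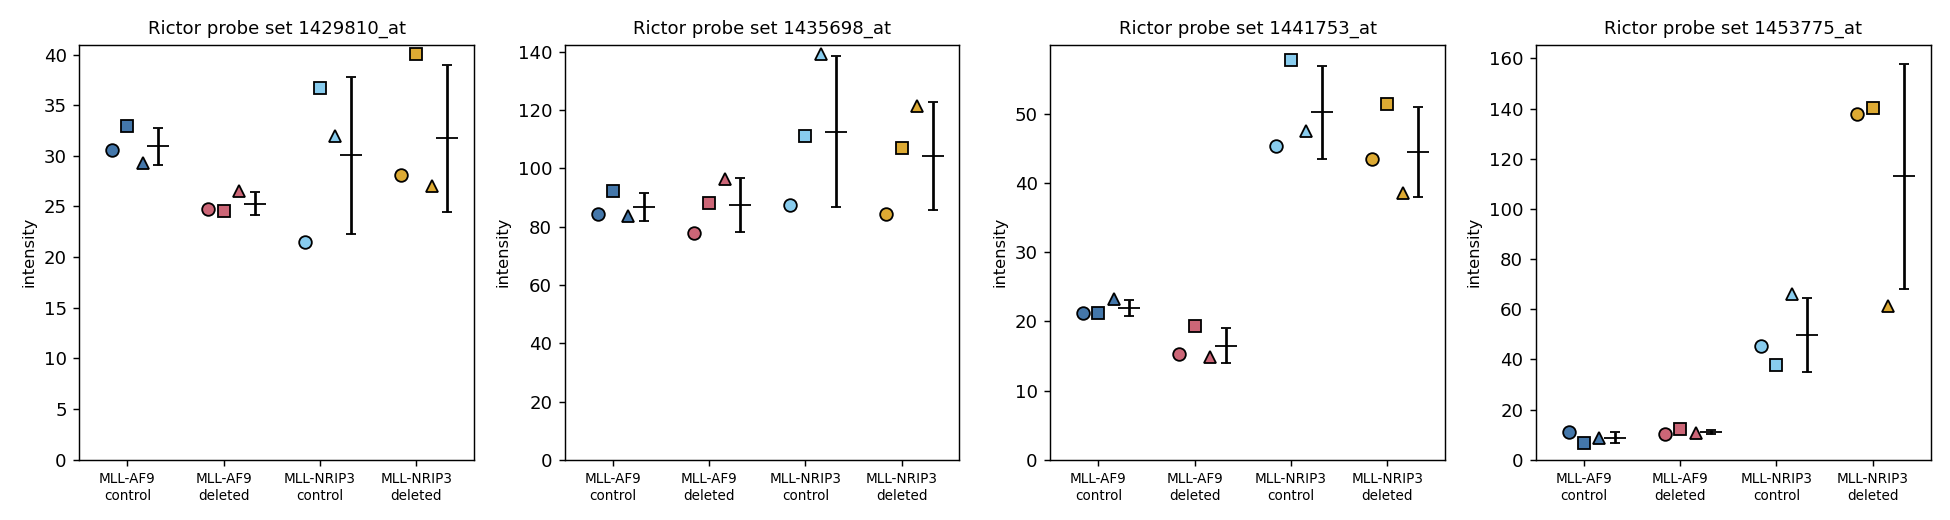
Intensity of 4 Rictor probe sets on each array (circle, square and triangle for replicates 1, 2 and 3) in the 4 groups, with the group mean and SD beside the points (n = 3). Probe set 1435698_at has means of 86.8 and 87.5 in MLL-AF9 and 113 and 104 in MLL-NRIP3 leukemia, and 1453775_at is higher in Rictor-deleted MLL-NRIP3 cells (113 against 49.7).

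The first comparison asked what changed with Rictor deletion in MLL-AF9 leukemia. Several neutrophil transcripts were among the largest increases. Wfdc21 rose 9.10-fold, from 114 ± 59.6 to 1099 ± 181 (SD, n = 3 each), Fpr2, a formyl peptide receptor of phagocytes, 8.90-fold, and Cd177, a neutrophil surface protein, 7.36-fold, with limma adjusted p of 0.0025, 0.0024 and 7.3e-05. Lrg1 rose 7.02-fold, Stfa2l1 and Stfa3, which encode stefin A cysteine protease inhibitors, 6.58- and 5.84-fold, the integrin gene Itgb2l 6.29-fold and Mgst2 6.26-fold. Transcripts of eosinophil granule proteins fell, Prg3 4.41-fold from 513 ± 61.8 to 106 ± 29.4 (adjusted p = 5.9e-04) and Prg2 3.07-fold (SD, n = 3 each, adjusted p = 0.020). Angpt1, which encodes angiopoietin 1, a ligand of the receptor Tie2, fell 3.06-fold, from 75.6 ± 19.7 to 13.7 ± 5.05 (adjusted p = 0.0063). The call of Prg2 ended without any 1 of the 6 MLL-AF9 arrays (adjusted p from 0.070 to 0.10), and that of Stfa3 without any 1 except control array 2 (0.056 to 0.095).

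Other genes among the largest decreases were Psma8 (2.42-fold), Adgrl4 (2.34-fold), Hpgd (2.27-fold), Camk1d (2.20-fold), Il17rb (2.18-fold) and Fcna (2.15-fold). The call of Camk1d ended without control array 1, 2 or 3 or Rictor-deleted array 2 (adjusted p from 0.070 to 0.12), and that of Psma8 without Rictor-deleted array 2 (0.055). Rps4l rose 6.39-fold, from 5.70 ± 2.21 to 122 ± 8.89. The sex-linked genes were among the largest changes in both directions. Xist, the RNA of the inactive X chromosome, fell from 2387 ± 48.5 to 98.5 ± 95.0, and the Y-linked Eif2s3y rose from 4.97 ± 2.46 to 162 ± 20.9 (SD, n = 3 each). The log2 fold change of Xist went from −4.70 to −5.34 without Rictor-deleted array 2. Thus in MLL-AF9 leukemia the genotype and the sex of the leukemia cells cannot be told apart. Kit (log2 fold change −0.39 ± 0.16 SE, adjusted p = 0.44) and Ptprc, which encodes CD45 (0.03 ± 0.09 SE, adjusted p = 1.0), did not pass the threshold.

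In all, 174 of 12582 genes were called in MLL-AF9 leukemia, 117 higher and 57 lower, and 70 of them changed at least 2-fold (log2 fold change of at least 1). With array weights the balance turned to 484 higher and 572 lower. The replicates of this model were close, with a median SD per gene of 0.08 in controls and 0.06 in deleted cells on the log2 scale, against 0.15 and 0.14 in MLL-NRIP3 leukemia. When the 6 MLL-AF9 arrays were fitted alone, 1039 genes were called, 477 higher and 562 lower, and all 174 were among them. Leaving out 1 of the 6 MLL-AF9 arrays at a time left between 83 and 115 calls, and without MLL-NRIP3 control array 3 there were 294.

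Of 35 gene lists fixed in advance, the mature neutrophil list had the largest shift in MLL-AF9 leukemia. All 27 tested members had a positive log2 fold change, with a median of 1.19, 11 were called higher and 16 were not called, and 23 were higher when adjusted over the list alone. The camera adjusted p was 3.7e-37 and remained at 0.014 with an estimated correlation between genes. Ceacam10 rose by 2.07 ± 0.22 (SE) on the log2 scale, the siderophore-binding Lcn2 by 2.30 ± 0.25 and the collagenase gene Mmp8 by 1.19 ± 0.16. In the primary granule and promyelocyte list (median 0.22 over 17 members, camera adjusted p = 4.0e-05), Ms4a3 and Serpinb1a were called higher, by 1.28 ± 0.19 and 0.50 ± 0.09, and Fcnb was at 2.23 ± 0.51 (adjusted p = 0.056). Its set test gave adjusted p = 0.23 with an estimated correlation, and 6 members were higher adjusted over the list alone.

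The cell cycle lists shifted slightly upward. In the G2/M and mitosis list 38 of 39 members had a positive log2 fold change, with a median of 0.22 (camera adjusted p = 1.8e-10), and none was called, over all genes or adjusted over the list alone. In the G1/S and DNA replication list 34 of 38 did, with a median of 0.12 (adjusted p = 4.7e-07), and Rrm2, a subunit of ribonucleotide reductase, was called, at 0.59 ± 0.07 (SE). Both had adjusted p = 0.48 with an estimated correlation. The mast cell, basophil and eosinophil list shifted downward (median −0.33 over 10 members, camera adjusted p = 1.0e-04, 2 called lower, 4 adjusted over the list alone, adjusted p = 0.23 with an estimated correlation). The monocyte and macrophage list also did (median −0.17 over 30 members, adjusted p = 0.0024), with 5 members called lower, among them the mannose receptor gene Mrc1 and the complement genes C1qa, C1qb and C1qc, whose log2 fold changes lay between −0.83 and −0.54. Adjusted over the list alone, 6 were lower and 2 higher. The set test gave adjusted p = 0.48 with an estimated correlation and 0.25 with the filter on dim genes at the 60th percentile. Without Rictor-deleted array 2 the G1/S median was 0.07, and without control array 1 or Rictor-deleted array 2 the monocyte median was −0.10.

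Small downward shifts were also called by camera for the lists of MLL fusion targets (median −0.13), HSC identity (−0.03), MYC targets and ribosome biogenesis (−0.11), B lineage (−0.11), dendritic cells and MHC class II (−0.11), autophagy and lysosome (−0.07) and ribosomal proteins (−0.04). Their adjusted p lay between 0.014 and 0.036, and between 0.48 and 0.76 with an estimated correlation. Each of these 7 calls ended without at least 1 array: 6 without control array 1 (adjusted p from 0.082 to 0.32), 5 without Rictor-deleted array 2 (0.12 to 0.24), 3 without Rictor-deleted array 1 (0.059 to 0.16), 2 without control array 3 (0.051 and 0.065), 1 without control array 2 (0.16) and 3 without MLL-NRIP3 deleted array 3 (0.067 to 0.079). Without control array 1 the medians of HSC identity, MYC targets, B lineage, dendritic cells, autophagy and ribosomal proteins were −0.01, −0.07, −0.06, −0.05, −0.03 and −0.02. Without Rictor-deleted array 2 the HSC identity median changed sign, to 0.01, and that of dendritic cells was −0.03. Those of HSC identity and MYC targets were −0.06 and −0.07 without Rictor-deleted array 1, and that of autophagy −0.11 without control array 3. The filter at the 60th percentile ended the calls of B lineage and autophagy (camera adjusted p of 0.85 and 0.074). Those of HSC identity and ribosomal proteins ended without a filter on dim genes (0.070 each). Quantile normalization ended those of autophagy and dendritic cells (0.057 and 0.086). Eya1 (MLL targets), Angpt1 (HSC identity), Jchain (B lineage), Cd209a and H2-DMa (dendritic cells) were called lower. Adjusted over the list alone, 2 MLL targets were lower and 1 higher, 4 HSC, 1 B lineage and 2 dendritic cell genes were lower, and none of the other 3 lists. The lists of quiescence regulators (median −0.03, adjusted p = 0.83), mTOR complexes and AKT signalling (0.02, 0.61), FOXO targets (−0.05, 0.21) and immediate early and handling stress (0.01, 0.50) did not pass the threshold, nor did the other 18 lists (adjusted p from 0.090 to 0.95).

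**Figure D2:**
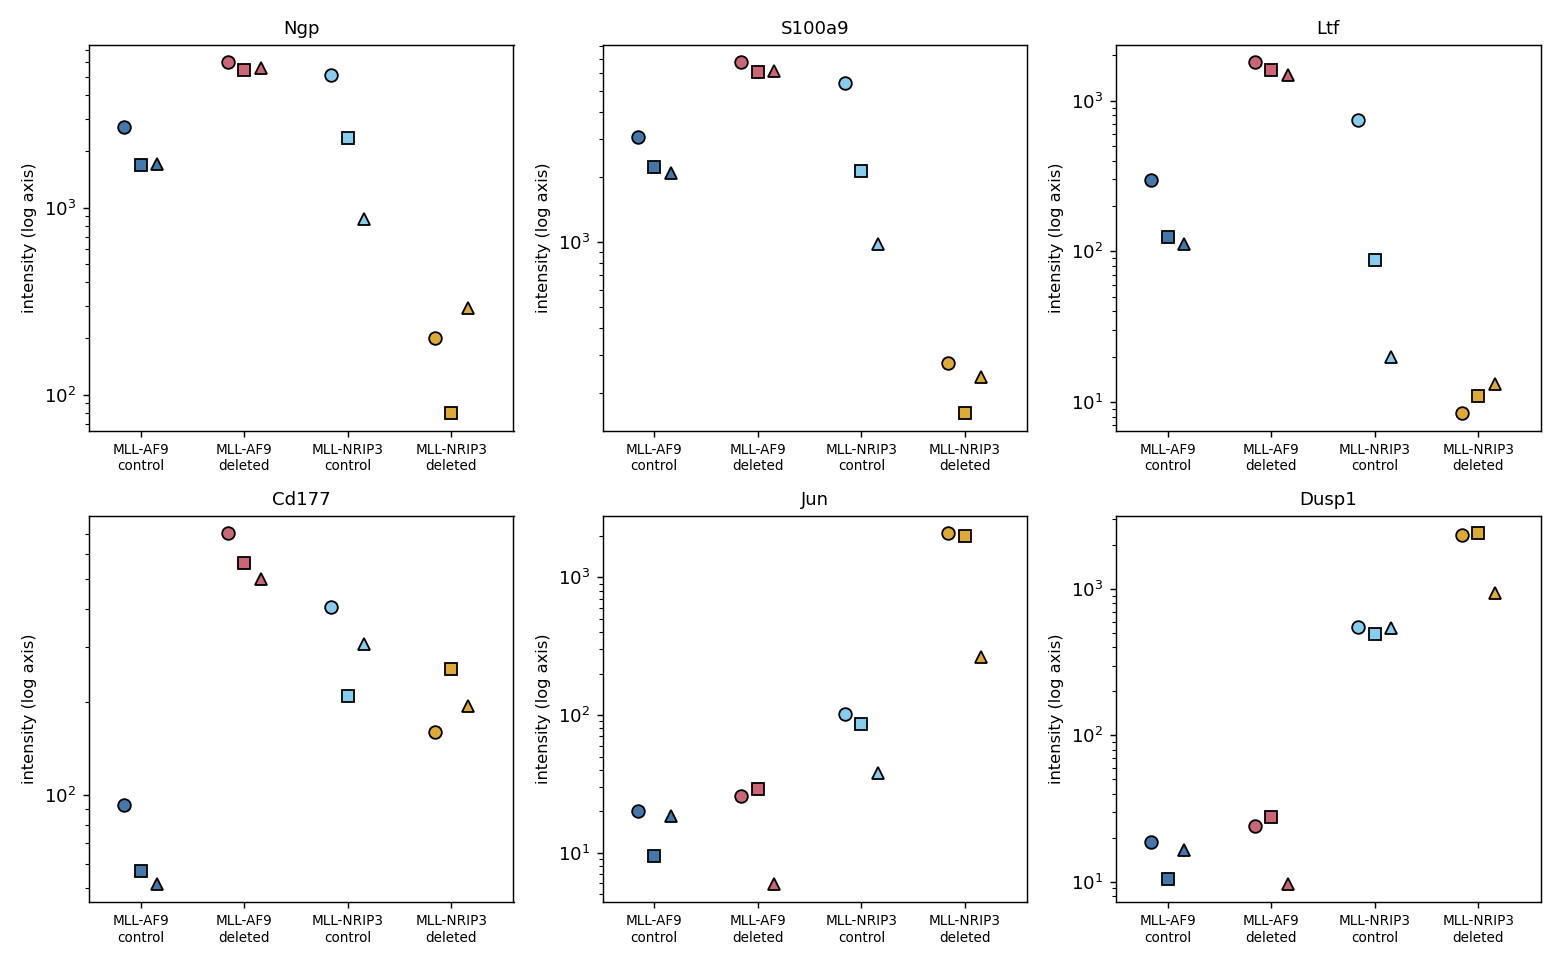
Intensity on a log axis of 4 mature neutrophil genes (Ngp, S100a9, Ltf, Cd177) and 2 immediate early genes (Jun, Dusp1) on each array, with circle, square and triangle for replicates 1, 2 and 3 and no mean drawn. Ngp is higher on the 3 Rictor-deleted MLL-AF9 arrays than on their controls (means 5683 and 2039) and lower on the 3 Rictor-deleted MLL-NRIP3 arrays (means 191 and 2780).

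The second comparison asked the same of MLL-NRIP3 leukemia. Here several neutrophil transcripts were among the largest decreases, and 10 of the 27 members of the mature neutrophil list were called lower and 1 higher. Ngp, a granule protein, fell 11.9-fold, from 2780 ± 2141 to 191 ± 106, Camp, the cathelicidin, 9.86-fold, and S100a9 and S100a8, the subunits of calprotectin, 9.59- and 5.07-fold (SD, n = 3 each, limma adjusted p from 6.9e-04 to 0.0038). Stfa2l1 fell 7.31-fold, from 243 ± 196 to 13.7 ± 5.59. Ighm, the immunoglobulin mu chain, fell 8.54-fold, the homeobox gene Irx5 5.48-fold, Tctex1d1 5.43-fold, the choline dehydrogenase gene Chdh 4.98-fold and Zfp783 4.39-fold. Jun, an AP-1 transcription factor subunit, rose 12.2-fold, from 75.4 ± 33.2 to 1445 ± 1025, and the mast cell protease Cpa3 6.47-fold, from 104 ± 6.63 to 952 ± 668 (SD, n = 3 each). Single arrays moved these sizes on the log2 scale. Without control array 1, Ngp, Camp and S100a9 went from −3.58, −3.30 and −3.26 to −2.97, −2.56 and −2.63, and without control array 3 to −4.23, −4.0 and −3.85, with Ighm going from −3.10 to −3.81. Jun went from 3.6 to 4.56 without Rictor-deleted array 3, Cpa3 from 2.69 to 3.39 without Rictor-deleted array 2, Irx5 from −2.45 to −1.87 without Rictor-deleted array 1 and Tctex1d1 from −2.44 to −1.83 without Rictor-deleted array 3.

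Several genes were near the floor in MLL-NRIP3 controls and bright in deleted cells. Rps4l rose from 3.37 ± 0.33 to 150 ± 46.7, Trim30d from 5.45 ± 1.15 to 112 ± 13.4 and Trim12a from 2.76 ± 0.75 to 80.3 ± 14.8 (SD, n = 3 each, adjusted p from 4.3e-07 to 1.1e-06). Trim30d and Trim12a read 145 and 90.4 in MLL-AF9 controls, and 119 and 97.1 in deleted cells of that model. A bright signal of these Trim genes thus did not require Rictor deletion. Glb1l2 rose 8.42-fold, Tmem98 6.25-fold, Vill, which encodes a villin-like protein, 5.72-fold, the WNT-binding Frzb 5.58-fold and Rab38 5.18-fold. The log2 fold change of Frzb went from 2.48 to 3.13 without Rictor-deleted array 2 and to 1.55 without Rictor-deleted array 3. Kit rose from 341 ± 43.7 to 524 ± 102 (SD, n = 3 each, adjusted p = 0.029, or 0.13 with the MLL-NRIP3 arrays fitted alone), a call that also ended without control array 1 or Rictor-deleted array 1 or 3 (0.073 to 0.10), without control arrays 1 and 2 (0.12) and with the hybridization control signal as a covariate (0.24). Ptprc (log2 fold change −0.02 ± 0.09 SE), Xist (−0.20 ± 0.38) and Eif2s3y (−0.03 ± 0.10) did not pass the threshold. Xist was between 2509 and 3558 and Eif2s3y under 4 on all 6 arrays.

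The fit of all 12 arrays called 1724 genes in MLL-NRIP3 leukemia, 748 higher and 976 lower. The balance turned to 1871 higher and 1457 lower with array weights, and to 1176 higher and 820 lower without Rictor-deleted array 3. The fit shares its estimate of the spread with the tighter MLL-AF9 arrays, and with the 6 MLL-NRIP3 arrays alone 196 genes were called, 100 higher and 96 lower, all of them among the 1724. In arrays simulated with the spread of each model and 200 changed genes, the fit of all arrays called 120 unchanged genes among 297 calls in MLL-NRIP3 leukemia, against 4 among 148 with the model's own arrays. So the share of false calls among the 1724 may exceed the threshold of 0.05. Its size is not known, since it depends on how many genes change. The simulated noise was also independent between genes, which that of the arrays need not be. Of the 20 genes named above by size, 18 were called in both fits; Camp and Frzb had adjusted p of 0.062 and 0.11 with the model's own arrays.

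The 3 MLL-NRIP3 control arrays also differed from each other. Control arrays 1 and 2 had a mean log2 signal of the hybridization controls of 10.69 and 9.99, against 8.53 to 8.77 on control array 3 and the 3 deleted arrays. Their ratio of the 5′ to the 3′ Gapdh control probe sets was 0.562 and 0.738, against 0.881 to 0.965 on the other 4. The same ratio for Actb was 0.448 and 0.474, against 0.614 to 0.714. The mean log2 signal of the polyA control probe sets was 9.96 and 9.07, against 6.44 to 7.90. Control array 3 correlated across genes with the deleted arrays (mean r = 0.977) no less than with its fellow controls (mean r = 0.974). Without control arrays 1 and 2, a choice made after seeing the data, 730 genes were called, of which 477 were among the 1724, and without control array 3 alone 3054 were. With the hybridization control signal as a covariate, also chosen afterwards, 509 genes were called. Of the 20 genes named by size, Camp, Frzb and Tctex1d1 lost their call without control arrays 1 and 2 (adjusted p of 0.058, 0.12 and 0.059), at log2 fold changes of −1.91, 2.43 and −2.14 against −3.30, 2.48 and −2.44 with all arrays. These, Irx5 and Chdh lost it with the covariate (0.053 to 0.12), at −2.06, 2.39, −2.14, −1.87 and −1.82. MLL-AF9 control array 3 also stood apart in its model, with a mean log2 polyA signal of 7.69 against 4.91 to 5.69. Its Gapdh and Actb ratios were 0.901 and 0.521, against 1.01 to 1.09 and 0.607 to 0.667 on the other MLL-AF9 arrays.

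**Figure D3:**
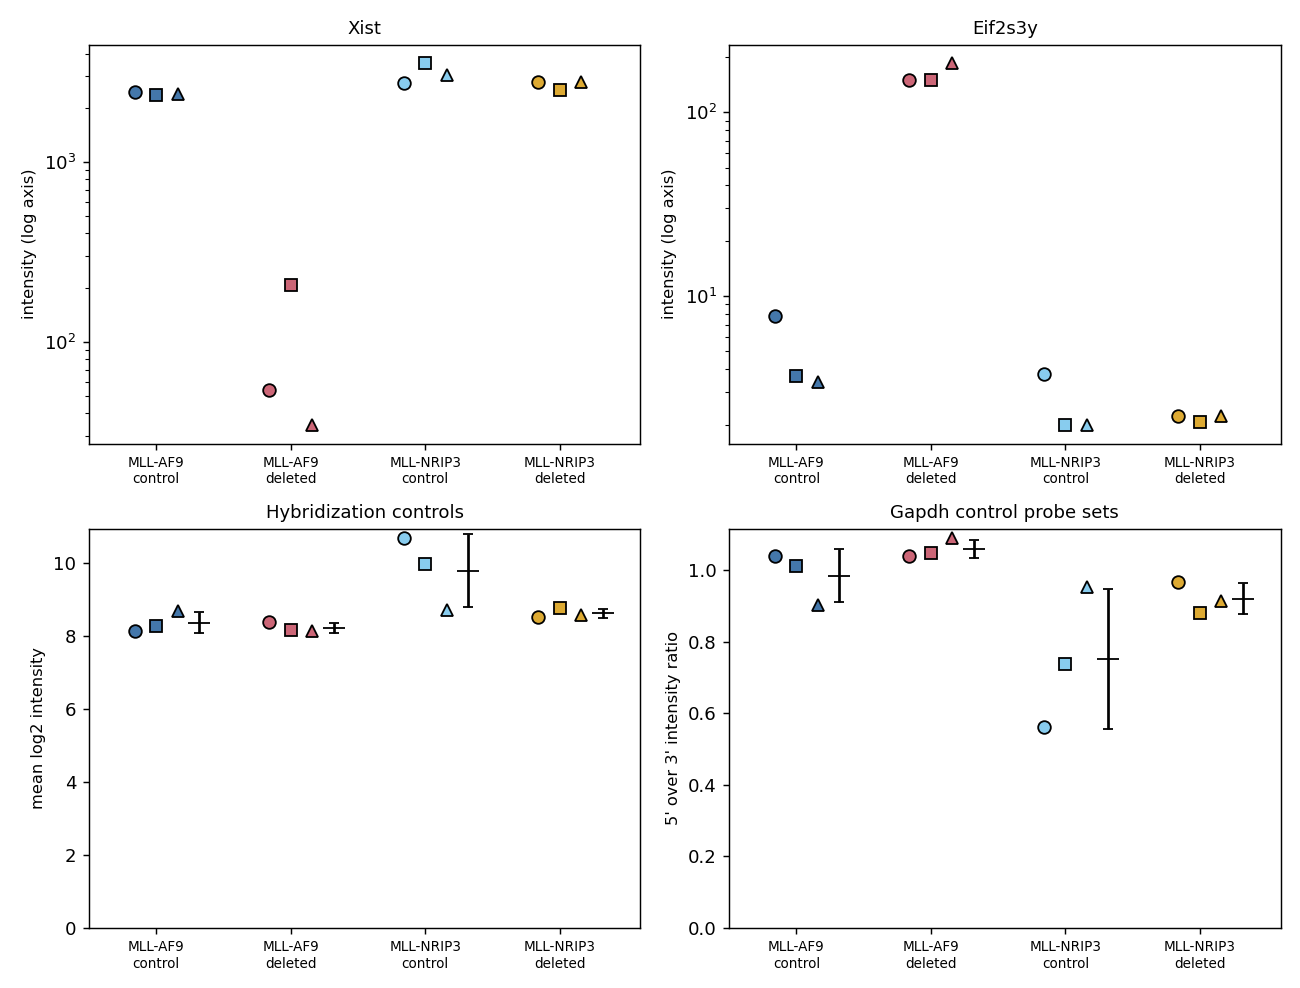
Xist and Eif2s3y intensity (log axes, no mean drawn), the mean log2 signal of the hybridization controls and the ratio of the 5′ to the 3′ Gapdh control probe sets on each array, with circle, square and triangle for replicates 1, 2 and 3. Bars in the lower panels give the group mean and SD (n = 3). Xist is high in MLL-AF9 controls and low in deleted cells, and MLL-NRIP3 control arrays 1 and 2 have control signals of 10.69 and 9.99.

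Among the lists, immediate early and handling stress genes had the largest median shift in MLL-NRIP3 leukemia, 0.82 over 30 members (camera adjusted p = 2.4e-09, adjusted p = 0.44 with an estimated correlation), or 0.49 without Rictor-deleted array 2. Of these, 17 were called higher and none lower, 21 were higher adjusted over the list alone, and 3 were called with the model's own arrays. Besides Jun, Socs3 rose by 0.94 ± 0.15 (SE) on the log2 scale, Atf3 by 1.26 ± 0.22 and the chaperone gene Hspa8 by 0.30 ± 0.05. The mature neutrophil list had a median of −0.61 over 27 members (adjusted p = 1.1e-05, or 0.44 with an estimated correlation), with 10 called lower and 1 higher, or 15 and 2 adjusted over the list alone; 7 were lower with the model's own arrays. Olfm4 and Padi4 both fell by 1.56 on the log2 scale (SE 0.17 and 0.19). On the control arrays, Ngp varied from 5098 on control array 1 to 2367 and 875 on control arrays 2 and 3, an order shared by the hybridization control signal. The ATF4 and unfolded protein response list had a median of 0.25 (adjusted p = 3.2e-05, or 0.44 with an estimated correlation), with 12 of 34 members called higher, 14 higher and 1 lower adjusted over the list alone, and 1 called with the model's own arrays, the lipoprotein receptor gene Vldlr (1.61 ± 0.10 SE). The self-contained test fry gave adjusted p = 0.018 for each of the 3 lists.

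The mast cell, basophil and eosinophil list (median 0.27 over 10 members, adjusted p = 0.042) had 5 members called higher, among them Cpa3, Ms4a2, the beta subunit of the IgE receptor, and Hdc, which makes histamine (1.32 ± 0.13 SE). The same 5 counted as higher adjusted over the list alone. The quiescence regulator list (median 0.17 over 31 members, adjusted p = 0.027) had 10 called higher and 2 lower, or 12 and 3 adjusted over the list alone. Klf4 (1.87 ± 0.38), Egr1 (1.30 ± 0.31) and Klf6 (1.55 ± 0.39) rose, and Smad3 fell by 0.99 ± 0.16 (SE); Egr1 and Klf6 are also members of the handling stress list. The homing, adhesion and cytoskeleton list (median −0.16 over 37 members, adjusted p = 0.023) had 10 called lower, led by the integrin gene Itgal (−1.38 ± 0.15 SE), and 3 higher, or 12 and 4 adjusted over the list alone. Their adjusted p was 0.52, 0.44 and 0.47 with an estimated correlation, and the calls of the last 2 ended without control arrays 1 and 2 (adjusted p = 0.19 and 0.57). Without 1 array, the mast cell call ended for control array 1 or 3 or Rictor-deleted array 1 or 3 (adjusted p from 0.050 to 0.19), the quiescence call for control array 2 (0.062) and the homing call for control array 1 or 2 or Rictor-deleted array 1 (0.054 to 0.055). The quiescence median was 0.27 without control array 3. The mast cell median was −0.01 without a filter on dim genes (adjusted p = 0.16).

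Lists of G1/S and DNA replication (median 0.16, adjusted p = 0.0080, 4 called higher), oxidative phosphorylation (0.10, 0.0099, 6 higher), DNA repair (0.12, 0.047, 2 higher) and autophagy and lysosome (−0.15, 0.048, 4 lower) shifted slightly, with adjusted p between 0.62 and 0.73 with an estimated correlation. Adjusted over the list alone, the counts were 4 and 6 higher, 0, and 4 lower, and no member of these 4 lists was called with the model's own arrays. The calls of the second and the fourth ended without control arrays 1 and 2 (adjusted p = 0.77 and 0.76). Without 1 array, the second ended for control array 2 (0.11), the third for control array 3 or Rictor-deleted array 1 or 2 (0.10 to 0.22), and the fourth for control array 1 or 2, Rictor-deleted array 3, MLL-AF9 control array 2 or MLL-AF9 deleted array 3 (0.051 to 0.23). The oxidative phosphorylation median was 0.05 without control array 2 and 0.15 without control array 3 or Rictor-deleted array 3, and the DNA repair median 0.07 without Rictor-deleted array 2. The autophagy median was −0.09 without control array 1, −0.23 without Rictor-deleted array 2 and −0.04 without Rictor-deleted array 3. The lists of G2/M and mitosis (median 0.05, adjusted p = 0.43), mTOR complexes and AKT signalling (−0.15, 0.28), FOXO targets (−0.06, 0.43), HSC identity (0.13, 0.095) and MLL fusion targets (0.16, 0.081) did not pass the threshold, nor did the other 20 lists.

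The third comparison tested whether the response to Rictor deletion differed between the models, as an interaction term. Its MLL-AF9 side also differs in sex, and its MLL-NRIP3 side includes control arrays 1 and 2 with their unlike control signals. Neither can be told apart from genotype, so the differences need not be responses to Rictor deletion alone. The comparison called 542 genes, with 245 responses higher in MLL-NRIP3 and 297 higher in MLL-AF9 leukemia. Without MLL-NRIP3 control array 3 it called 1397 genes, without Rictor-deleted array 3 of that model 947 (592 higher in MLL-NRIP3 and 355 higher in MLL-AF9), and without Rictor-deleted array 1 of MLL-AF9 311. With array weights 1491 responses were higher in MLL-NRIP3 and 1031 in MLL-AF9 leukemia. The mature neutrophil list differed most, with a median difference of −2.23 on the log2 scale and 20 of 27 members called (21 adjusted over the list alone, camera adjusted p = 4.0e-23, adjusted p = 0.062 with an estimated correlation). For Ltf, lactoferrin, the means were 179 ± 104 and 1628 ± 160 in MLL-AF9 and 283 ± 398 and 10.9 ± 2.36 in MLL-NRIP3 leukemia (SD, n = 3 each), control and deleted in turn. The difference was −5.60 ± 1.09 (SE). The MLL-NRIP3 control mean rests on control array 1 (741, against 87.9 and 19.9 on control arrays 2 and 3), and the difference was −4.38 without it and −6.58 without control array 3; leaving out 1 array at a time gave adjusted p of 0.040 or lower. Angpt1 went the opposite way, from 75.6 to 13.7 in MLL-AF9 and from 232 to 500 in MLL-NRIP3 leukemia (difference 2.71 ± 0.36, adjusted p = 0.0012). So did Psma8, from 96.6 to 31.5 and from 5.63 to 87.4 (3.50 ± 0.31, adjusted p = 5.6e-05).

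The lists of MLL fusion targets and HSC identity each had 4 members whose response differed, none in the opposite direction, with 8 and 5 adjusted over the list alone. Their camera adjusted p was 0.0077 and 0.013, and 0.40 for both with an estimated correlation. Among MLL fusion targets (median difference 0.29), Hoxa5 differed by 1.61 ± 0.25, Runx1 by 1.11 ± 0.18, Meis1 by 0.93 ± 0.22 and Hoxa9 by 0.64 ± 0.15 (SE), all higher in MLL-NRIP3. In the HSC identity list (0.19) Cd34 differed by 1.85 ± 0.30 and Gata2, also a member of the mast cell list, by 0.94 ± 0.21. Kit, a member of the mast cell list and not of the HSC identity list, differed by 0.98 ± 0.22 (limma adjusted p = 0.026). The mast cell, basophil and eosinophil list differed by a median of 1.16 (adjusted p = 1.0e-05, 5 of 10 called, 7 adjusted over the list alone). Its members did not all move alike. The eosinophil genes Prg3 and Prg2 fell in MLL-AF9 leukemia and were dim in MLL-NRIP3 leukemia (49.8 to 35.3 and 46.7 to 37.8). The mast cell gene Cpa3 went from 322 to 276 in MLL-AF9 and from 104 to 952 in MLL-NRIP3 leukemia. The immediate early and handling stress list differed by 0.73 (adjusted p = 3.2e-07, 4 of 30 called, 15 adjusted over the list alone). With an estimated correlation the last 2 lists had adjusted p of 0.19 and 0.40. The call of Kit ended without MLL-AF9 control array 1 or 3 or deleted array 1 or 3, or MLL-NRIP3 control array 1 or deleted array 1 (0.056 to 0.075). The HSC identity call ended without MLL-NRIP3 control array 3 or deleted array 3 (0.063 and 0.099).

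**Figure D4:**
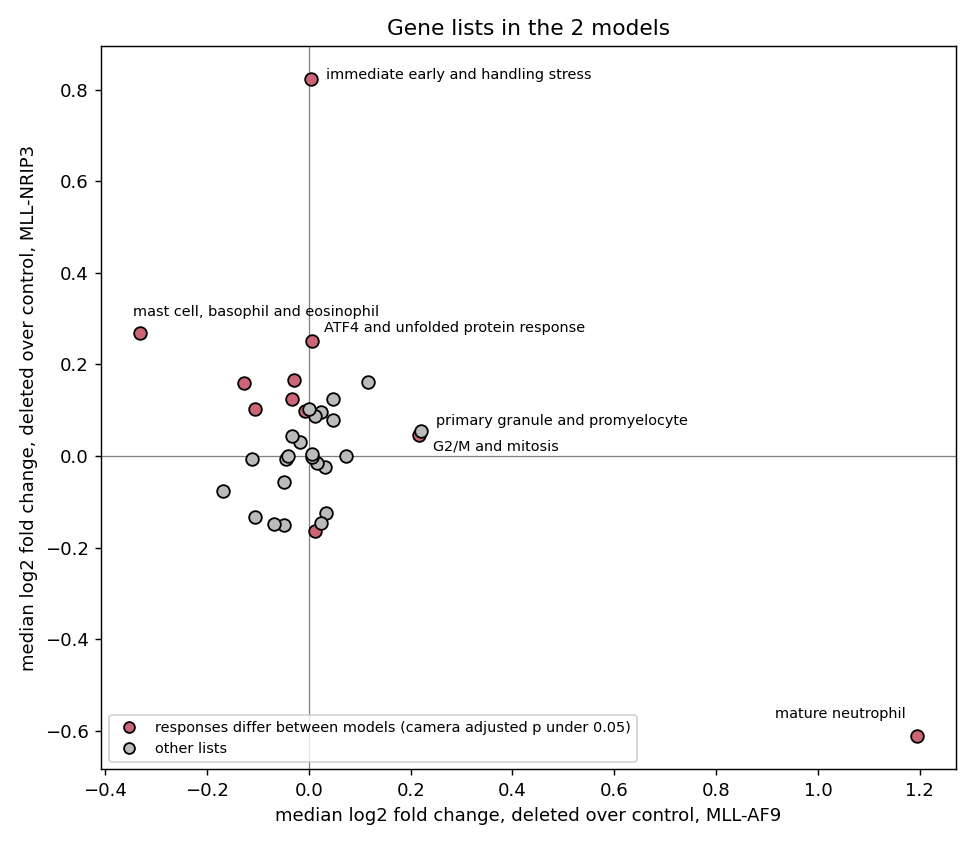
Median log2 fold change of each of the 35 lists with Rictor deletion in MLL-AF9 leukemia (horizontal axis) and in MLL-NRIP3 leukemia (vertical axis). The mature neutrophil list lies at 1.19 and −0.61, and the immediate early and handling stress list at 0.01 and 0.82. Filled red points are the 11 lists whose responses differed by camera with a preset correlation.

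Few genes were called in the same direction in both models. Of the 117 genes higher in MLL-AF9 leukemia, 6 were also called higher in MLL-NRIP3 leukemia (Asns, Lmo1, Mansc1, Megf9, Rps4l and Vill), where independent lists would share 6.96. By contrast 30 were called lower there, against 9.08 for independent lists (Fisher's exact test, 2-sided, adjusted p = 1.3e-08 over 4 overlaps). Among the 30 were Fpr2, Itgb2l, Stfa2l1, Stfa3, Olfm4, Trem3 and Itgal. Fisher's test takes genes as independent, but several of the 30 are neutrophil transcripts, which moved together. Both sets of calls also came from the same fit, with a shared estimate of the spread of each gene. The adjusted p may therefore be too small, and the overlap in part restates the opposite shifts of neutrophil genes. The counts also depend on the fit, which called 174 genes in MLL-AF9 and 1724 in MLL-NRIP3 leukemia. With each model's own arrays 1039 and 196 were called, so the model with more calls changed. The overlap of those own-array calls was not tested. Of the 57 genes lower in MLL-AF9 leukemia, 6 were also lower in MLL-NRIP3 (Cenpv, Krt18, L3mbtl3, Nnt, Ttc4 and Usp24) against 4.42 for independent lists, and 6 were higher against 3.39. The controls of the models are separate arrays. Across the 12582 genes, which are not independent replicates, the log2 fold changes of the models had r = −0.01 and rho = 0.12.

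The average over both models called 844 genes, 356 higher and 488 lower, of which 33 changed at least 2-fold. Without MLL-NRIP3 control array 3 it called 2215 genes, and without Rictor-deleted array 2 of MLL-AF9 345. The balance turned to 676 higher and 531 lower without Rictor-deleted array 3 of MLL-NRIP3, to 1629 and 1525 with array weights, and was 24 and 9 among the 33. Rps4l rose 7.30-fold and Vill 3.79-fold, and both were called higher in each model. Rps4l read 3.07 to 8.11 on the control arrays of both models and 115 to 203 on the deleted arrays. Such a change from the floor to a bright signal leaves a variant carried by the donors open. Cenpv, a centromere protein gene, fell 2.61-fold, Tctex1d1 3.41-fold, Chdh 2.95-fold, Ighm 3.19-fold and the peptidase gene Dpp4 3.09-fold. The transcription factor gene Ikzf2 fell 2.19-fold, Pecam1, an adhesion molecule of endothelium and leukocytes, 2.13-fold and the RNA-binding Lin28a 1.97-fold. Wfdc21 and Klf6 were 4.10- and 2.37-fold higher. Of the 20 largest averages, 12 belonged to genes whose responses differed between the models (interaction adjusted p of 0.043 or lower). These were Ighm, Cenpv, Ikzf2 and Lin28a, all with the larger decrease in MLL-NRIP3 leukemia, and Xist, Eif2s3y, Jun, Glb1l2, Tmem98, Cpa3, Lrg1 and Prg3. The interaction call of Jun ended without any 1 array except MLL-NRIP3 control array 3 and deleted array 3 (adjusted p from 0.053 to 0.11). The average call of Cpa3 ended without any 1 array except MLL-NRIP3 control array 3 and deleted arrays 2 and 3 (0.056 to 0.082). That of Jun ended without MLL-AF9 control array 1, 2 or 3 or deleted array 1 or 2, or MLL-NRIP3 deleted array 1 or 2 (0.054 to 0.074), and that of Klf6 without MLL-AF9 control array 3 or deleted array 1 or 2, or MLL-NRIP3 deleted array 1 (0.051 to 0.062). With the hybridization control covariate the average calls of Cpa3 and Klf6 ended (limma adjusted p of 0.18 and 0.089), as did the interaction call of Cpa3 (0.063). Ighm, for example, went from 1250 to 1045 in MLL-AF9 and from 689 to 51.8 in MLL-NRIP3 leukemia. The G1/S and DNA replication list (median 0.14, camera adjusted p = 1.9e-06, 5 of 38 called higher, 13 adjusted over the list alone) and the ATF4 and unfolded protein response list (0.14, 4.1e-05, 8 of 34, 11 adjusted over the list alone) were higher on average, as was the immediate early and handling stress list (0.46, 6.2e-08, 8 of 30, 16 adjusted over the list alone). Asparagine synthetase (Asns), a target of ATF4, was higher by 0.56 ± 0.08 (SE). All 3 lists had adjusted p = 0.51 with an estimated correlation, and the handling stress median was 0.25 without MLL-NRIP3 deleted array 2. By camera, the responses of the ATF4 and handling stress lists were higher in MLL-NRIP3 leukemia, by medians of 0.29 and 0.73. Their averages therefore do not stand for a response of equal size in both models. Sex in MLL-AF9 leukemia and the unlike control signals of MLL-NRIP3 control arrays 1 and 2 also enter every average. Neither can be told apart from genotype.

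The last comparison set MLL-NRIP3 controls against MLL-AF9 controls. The values of the models were on different scales, as their medians show, and model and array set cannot be told apart. The median log2 difference over all genes was 0.46, and 8978 genes were called higher and 608 lower in MLL-NRIP3 cells. With quantile normalization across the 12 arrays the split was 3541 higher and 2865 lower, and with median centring 5013 and 1860. The genes named here exceeded that shift by far and were called under each of these scalings. Dlk1 and Meg3, neighbours in one imprinted locus, were at 1490 ± 1179 and 1322 ± 853 in MLL-NRIP3 controls and at 4.59 ± 0.59 and 12.3 ± 0.83 in MLL-AF9 controls (SD, n = 3 each). Clec4e, Rhoj, Hacl1, Muc13, Cgnl1 and the receptor gene Flt3 were 14.9- to 22.4-fold higher, and the immediate early genes Egr1 and Dusp1 18.5- and 17.6-fold. Without control array 2 of MLL-NRIP3, Dlk1 and Meg3 went from 5.72 and 5.27 to 6.62 and 5.97 on the log2 scale, and Dlk1 to 5.07 without control array 3. The chromatin organizer Satb1, Epha7, Il17rb, the MLL target Eya1, P2ry14 and Dennd5b were 9.11- to 14.4-fold lower, as were Dsp and Prg3, 8.67- and 8.37-fold (Dsp −3.12 on the log2 scale, or −2.29 without MLL-NRIP3 control array 3). Trim34a and Trim30d were 8.49- and 7.51-fold lower in MLL-NRIP3 controls.

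Camera, which compares a list with the other genes, called 13 lists between the controls. Relative to the other genes, the lists of sterol and fatty acid synthesis (median 1.22, camera adjusted p = 0.031, 23 of 25 called higher) and glycolysis (0.90, 0.0078, all 18 called higher) were higher in MLL-NRIP3 controls. The B lineage list was lower (median −0.21, adjusted p = 1.3e-12, 10 of 17 called lower and 2 higher), led by Cd79b at −2.78 ± 0.18 (SE). Adjusted over the list alone, the counts were 24, 18 and 9 lower with 2 higher. With an estimated correlation the adjusted p was 0.88, 0.62 and 0.18. For the monocyte and macrophage list (median 0.10, adjusted p = 2.3e-08, or 0.32 with an estimated correlation) the median was positive while the test gave lower, since the other genes differed by more. The same held for the lists of the interferon response (0.01, 4.4e-07), dendritic cells and MHC class II (0.20, 1.9e-04), mature neutrophils (0.34, 0.0080, 12 of 27 called higher and 2 lower), mast cells, basophils and eosinophils (0.06, 0.0080), megakaryocytes and platelets (0.19, 0.031) and HSC identity (0.19, 0.042). Camera gave higher for ribosomal proteins (0.47, 3.8e-04, 25 of 26 called higher), oxidative phosphorylation (0.49, 0.040) and antioxidant and NRF2 targets (0.56, 0.042). Against the median of 0.46 over all genes, however, ribosomal proteins and oxidative phosphorylation hardly differed in size. Counts of members called higher include the difference in scale between the models. With an estimated correlation the 9 lists from the interferon response on had adjusted p from 0.39 to 0.88.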

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

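The tests of neutrophils among the sorted cells, of donor sex, of a technical difference between arrays and of a strain variant were chosen after the results they bear on were seen. So was the use of group means for genes at the floor. The test of the segment around Rictor and the splits of the arrays were not.

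Responses to Rictor deletion that differed between the models by the interaction test are listed here as MLL-NRIP3 minus MLL-AF9 on the log2 scale. Sex in MLL-AF9 leukemia and a technical difference of MLL-NRIP3 control arrays 1 and 2 are not separated from genotype in them. The median difference was −2.23 for the mature neutrophil list, 1.16 for mast cells, basophils and eosinophils, 0.73 for immediate early and handling stress genes, 0.29 for the ATF4 and unfolded protein response, 0.29 for MLL fusion targets and 0.23 for quiescence regulators. It was 0.21 for MYC targets and ribosome biogenesis, 0.19 for HSC identity, 0.10 for oxidative phosphorylation, −0.12 for homing, adhesion and cytoskeleton and −0.15 for G2/M and mitosis. None of these 11 calls held with an estimated correlation (adjusted p from 0.062 to 0.82), and those of homing, MYC targets, oxidative phosphorylation and quiescence ended without MLL-NRIP3 control arrays 1 and 2 (0.084 to 0.83) and with the hybridization control covariate (0.059 to 0.45). Without 1 array, the G2/M call ended for MLL-AF9 control array 2 or deleted array 2 (0.097 and 0.11), MLL-NRIP3 deleted array 1 (0.17) and MLL-NRIP3 control array 3 (0.55). The oxidative phosphorylation call ended for MLL-NRIP3 control array 2 or deleted array 1 (0.16 and 0.084), the quiescence call for MLL-NRIP3 control array 2 (0.078) and the HSC identity call for MLL-NRIP3 control array 3 or deleted array 3 (0.063 and 0.099). The G2/M median was −0.29, −0.07 and −0.24 without MLL-NRIP3 control arrays 2 and 3 and deleted array 2, the homing median −0.22 without MLL-NRIP3 control array 3, the oxidative phosphorylation median 0.05 without control array 2 and the quiescence median 0.14 without deleted array 2 of that model. Neutrophil and granule genes had differences of −5.60 (Ltf), −5.59 (Stfa2l1), −5.08 (Ngp), −4.64 (S100a9), −4.64 (Camp), −4.61 (Fpr2), −4.45 (Stfa3), −3.94 (Itgb2l), −3.41 (Cd177), −3.37 (S100a8) and −2.60 (Lrg1). Further genes with a lower response in MLL-NRIP3 leukemia were Mgst2 (−4.09), Irx5 (−3.75), Zfp783 (−2.89), Ighm (−2.84), Ikzf2 (−1.69), Lin28a (−1.63) and Cenpv (−1.18). Higher responses there were those of Psma8 (3.50), Jun (3.48), Glb1l2 (3.04), Lipo3 (2.97), Cpa3 (2.91), Trim30d (2.84), Angpt1 (2.71), Tmem98 (2.62), Stx3 (2.59), Rab38 (2.42), Trim12a (2.26), Prg3 (1.84), Camk1d (1.81), Adgrl4 (1.47), Il17rb (1.08) and Fcna (0.85). The sex-linked Xist and Eif2s3y differed by 4.51 and −3.11. Without MLL-NRIP3 control array 1 the differences of Ltf, Ngp, S100a9, Camp, Fpr2 and Stfa3 were −4.38, −4.48, −4.01, −3.90, −3.97 and −3.75, and without its control array 3 the first 4 were −6.58, −5.74, −5.24 and −5.34. Jun and Lipo3 were at 4.44 and 3.63 without MLL-NRIP3 deleted array 3, Cpa3 at 3.61 without deleted array 2, Irx5 at −3.16 without deleted array 1, and Xist at 5.15 without MLL-AF9 deleted array 2.

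The mature neutrophil list shifted upward with Rictor deletion in MLL-AF9 leukemia, where all 27 members were positive, and downward in MLL-NRIP3 leukemia, where 10 were called lower and 1 higher, 22 were negative, and the adjusted p was 0.44 with an estimated correlation. A sex difference between donors is argued against in MLL-NRIP3 leukemia, where the list mean differed by −1.02 (SE 0.281) while Xist and Eif2s3y differed by −0.20 and −0.03. In MLL-AF9 leukemia sex and genotype cannot be told apart, since Xist differed by −4.70 and no array breaks the link. A varying share of mature neutrophils also stays open: 81.5% of members had the sign of the list in MLL-NRIP3 leukemia, where Chil3, one of the 5 brightest, was at 0.26 ± 0.32 (SE) and Ngp at −3.58, and whether the K+G– sort would remove neutrophils is unknown, since its label is not expanded in the sources used here. Altered differentiation of the leukemia cells after loss of Rictor may contribute and was not tested apart from these.

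The count of genes called in MLL-NRIP3 leukemia depends on the arrays used, among them control arrays 1 and 2. These had brighter hybridization controls and lower Gapdh 5′ to 3′ ratios than the other 4 arrays. The count fell further without Rictor-deleted array 1 than without control array 1 or 2 alone, and it rose without control array 3. With the hybridization control signal as a covariate 509 genes were called, 390 of them among the 1724. A technical difference of control arrays 1 and 2 may make up part of the calls, but the changes in the count do not show that it does. It cannot be told apart from genotype, with only 1 control array outside the pair. Whether it lies in the arrays, the RNA or its labelling was not tested. The handling stress median was 0.75 against control array 3 and 0.74 against control arrays 1 and 2 (ratio 1.02), and the mature neutrophil median −0.54 and −0.60 (ratio 0.893). These ratios rest on that 1 array and exclude nothing, and 4 of the 10 list calls in MLL-NRIP3 leukemia ended with the covariate, although not those of these 2 lists. Handling of the cells before lysis and a response to loss of Rictor both stay open for the stress genes, untested.

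Some autosomal genes were at an intensity under 16 on all 3 arrays of one genotype and at 64 or more on all 3 of the other: Ceacam10, Olfml2b and Rps4l in MLL-AF9, and Lin28a, Ms4a6d, Rps4l, Trim30d and Trim34a in MLL-NRIP3 leukemia. With group means in place of every array there were 35 such genes, among them these 7, Trim12a, Zfp783 and Stfa2l1. A segment carried with the Rictor allele is argued against for the 7, since 0 lay within 10 Mb of Rictor, but 1 of the 35 did (Rai14). Of 36 other genes tested within 10 Mb of Rictor, 0 were called in MLL-AF9 leukemia. In MLL-NRIP3 leukemia 8 were, against 1724 of 12582 over all genes (Fisher's exact test, 1-sided, p = 0.11). A strain variant of the donors is a candidate explanation for Trim30d and Trim34a, which lie within 1 Mb of each other, where 10000 random draws gave 0.0775 such genes on average (permutation p = 0.038), but by group means 5 of the 35 had such a neighbour against 2.14 in random draws (p = 0.098), so it stays open. Both genes belong to one family, whose shared regulation could give the same count, and no biological explanation was tested. Trim30d and Trim34a were bright in both MLL-AF9 groups (145 and 119, 180 and 167, control and deleted in turn). Only the MLL-NRIP3 controls had them near the floor, so their signal did not require Rictor deletion. Rps4l was near the floor in the controls of both models and bright in both deleted groups. It had no such neighbour, so the neighbour count does not bear on it.

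Other splits of the arrays were compared with the real ones. For each model and for the controls of both models, 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. The real split, the only 1 to reach its own count, called 174 genes in MLL-AF9 leukemia (highest other 0), 1724 in MLL-NRIP3 leukemia (343, with control arrays 1 and 2 beside deleted array 3) and 9586 between the controls (0). For the difference between the models, 2 of 100 splits called as many as the real 542, a share under 0.05, and the highest other called 844. That split exchanges the genotypes of MLL-NRIP3 leukemia and so equals the average. For the average, 1 of 100 splits, the real one, called 844, and the highest other called 542. All remaining splits mix control and deleted arrays in at least 1 model. Effects of genotype then widen the spread within groups and can lower the counts. The share under 0.05 therefore does not decide whether the responses of the models differ or are shared.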

How the results depend on the processing

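The omission of MLL-NRIP3 control arrays 1 and 2, the hybridization control covariate and the omission of sex-chromosome genes were chosen after seeing the data. The 20 genes named by size in each contrast kept their direction under every alternative that tested them; 9 in MLL-AF9, 15 in MLL-NRIP3, 14 in the difference, 14 in the average and 20 between the controls also kept their call there. Xist and Eif2s3y were not tested without sex-chromosome genes, nor Eif2s3y and, in MLL-NRIP3 leukemia, Frzb with the filter at the 60th percentile. In MLL-AF9 leukemia the unmoderated test ended the calls of Angpt1, Camk1d, Fpr2, Hpgd, Itgb2l, Lrg1, Prg2, Psma8, Stfa2l1, Stfa3 and Wfdc21 (adjusted p from 0.060 to 0.15), and in the difference those of Camp, Cpa3, Jun, Lipo3, Ltf and Stx3 (0.051 to 0.15). In the average it ended those of Cpa3, Dpp4, Ighm, Jun, Klf6 and Lrg1 (0.057 to 0.12). In MLL-NRIP3 leukemia Camp, Chdh, Frzb, Irx5 and Tctex1d1 lost their call with the covariate, and Frzb with the unmoderated test (0.063). The cause was not tested for the changes below, except that stricter or looser thresholds, more probe sets or fewer arrays change counts by construction. No depth is defined for arrays; dim genes near the floor limit the folds.

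The 174 genes called in MLL-AF9 leukemia became 1039 with its own arrays, 1056 with array weights, 65 with an unmoderated test, 70 at 2-fold or more, 359 without MLL-NRIP3 control arrays 1 and 2 and 271 with the covariate. The 1724 in MLL-NRIP3 leukemia became 196, 3328, 1108, 206, 730 and 509 in that order, 3207 probe sets when each was tested, and 2657 at an adjusted p under 0.1. The 542 of the difference became 2522 with array weights, 297 unmoderated, 884 probe sets, 234 at 2-fold or more and 954 at 0.1. The 844 of the average became 3154, 408, 1309, 33 and 1406 in that order, and 345 with the covariate. The 9586 between the controls became 19766 probe sets and 1700 at 2-fold or more. The share higher there was 93.7%, against 55.3% with quantile normalization and 72.9% with median centring.

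Of the list calls, 5 of 13 in MLL-AF9, 4 of 10 in MLL-NRIP3, 5 of 11 in the difference and 3 of 12 in the average were kept under every alternative run for lists, apart from the estimated correlation and fry. The estimated correlation ended all of these calls but that of the mature neutrophil list in MLL-AF9 leukemia. Fry ended 12 of 13 in MLL-AF9 (adjusted p from 0.12 to 0.56; mature neutrophils kept it), 4 of 10 in MLL-NRIP3 (G1/S, oxidative phosphorylation, DNA repair and autophagy, 0.10 to 0.20), 9 of 11 in the difference (0.052 to 0.56; mature neutrophils and mast cells kept it) and 11 of 12 in the average (0.075 to 0.39; the ATF4 list kept it). Leaving out 1 array at a time ended 7, 6, 4 and 7 of them. The replicate block ended 2 list calls in MLL-AF9 (autophagy and lysosome, ribosomal proteins) and 1 in MLL-NRIP3 leukemia (autophagy and lysosome), with adjusted p from 0.053 to 0.10, that of Rictor probe set 1453775_at (0.079) and those of Kit in MLL-NRIP3 leukemia (0.078) and in the difference (0.087).

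Leaving out 1 array at a time gave 83 to 294 genes in MLL-AF9 leukemia, 897 to 3054 in MLL-NRIP3 leukemia, 311 to 1397 for the difference, 345 to 2215 for the average and 8979 to 9896 between the controls. The MLL-AF9 count moved by over 1.5 times without any of its 6 arrays (111, 111 and 98 without control arrays 1, 2 and 3, and 93, 83 and 115 without deleted arrays 1, 2 and 3) and without MLL-NRIP3 control array 3 (294). The MLL-NRIP3 count did so without its control arrays 1, 2 and 3 (1057, 1111 and 3054) and deleted array 1 (897). The difference did so without MLL-AF9 control arrays 1 and 3 (342 and 330), its deleted arrays (311, 324 and 329), and MLL-NRIP3 control array 3 and deleted array 3 (1397 and 947). The average did so without each MLL-AF9 array (442, 411, 347, 374, 345 and 401), and MLL-NRIP3 control array 3 and deleted array 1 (2215 and 535).

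With the replicate number as a block, the counts were 142, 1327, 464, 576 and 9592 in the order above. Arrays with the same number did not visibly deviate together (correlations from −0.13 to 0.06). With 3 arrays per group this does not exclude that the numbers pair the samples.

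The values below changed sign, and none was called with its sign changed. The HSC identity median in MLL-AF9 leukemia was 0.0062 without Rictor-deleted array 2, although camera still gave lower. In MLL-NRIP3 leukemia these were Rictor probe set 1427583_at (−0.00038 with quantile normalization, −0.0081 with median centring) and 1429810_at (−0.076 with array weights), Ptprc (0.22 with the mean of probe sets, 0.073 with array weights) and Eif2s3y (0.015 without control arrays 1 and 2). Ptprc was at −0.00015 in MLL-AF9 leukemia with the covariate. For the difference, Rictor was at 0.21 and Ptprc at 0.11 with the mean of probe sets, and Ptprc at 0.038 with array weights. For the average, Rictor was at 0.050 with the mean of probe sets, and Ptprc at −0.0025 with median centring, −0.12 without control arrays 1 and 2 and −0.12 with the covariate. Between the controls, Rictor, Ptprc and Xist were at −0.18, −0.18 and −0.098 with quantile normalization, and Ptprc at −0.013 with median centring; Ptprc there had been called (adjusted p = 0.015). Leaving out 1 array at a time, further uncalled values ranged across 0. In MLL-AF9 leukemia these were Rictor probe sets 1427583_at (−0.0030 to 0.029) and 1435698_at (−0.055 to 0.074) and Ptprc (−0.024 to 0.059). In MLL-NRIP3 leukemia they were 1427583_at (−0.0087 to 0.017), 1429810_at (−0.085 to 0.16), 1435698_at (−0.24 to 0.057), Ptprc (−0.10 to 0.10) and Eif2s3y (−0.053 to 0.015). For the difference they were Rictor (−0.24 to 0.051) and Ptprc (−0.13 to 0.076), and for the average Rictor (−0.11 to 0.032) and Ptprc (−0.038 to 0.064).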

Other observations

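Further groups were described after the data were examined. On average over both models, the NF-kB and inflammation list shifted upward by camera (median 0.07, adjusted p = 0.031, or 0.67 with an estimated correlation, 6 of 25 called higher, 7 higher and 1 lower adjusted over the list alone), among them the chemokine gene Cxcl2 at 0.90 ± 0.15 and Nfkbiz at 0.79 ± 0.16 (SE). The primary granule list also shifted upward (median 0.25, adjusted p = 0.014, or 0.51 with an estimated correlation, 5 of 17 called higher, 6 adjusted over the list alone), with Cst7 at 0.76 ± 0.15 and Ms4a3 at 0.67 ± 0.13. The autophagy and lysosome list shifted downward (median −0.09, adjusted p = 0.011, or 0.67 with an estimated correlation, 4 of 34 called lower, 9 lower and 1 higher adjusted over the list alone), with the protease gene Ctsb at −0.44 ± 0.10 and Lamp1 at −0.29 ± 0.06. Without MLL-NRIP3 control array 3 the first and the second were no longer called (adjusted p = 0.25 and 0.051), nor was the first with the filter on dim genes at the 60th percentile (0.19), nor the third without control arrays 1 and 2 of that model (0.16) or with the hybridization control covariate (0.20). The primary granule median was 0.10 and 0.09 without MLL-NRIP3 control arrays 1 and 3, and the autophagy median −0.13 without control array 3. Of the 12 lists called on average, the others were mature neutrophil, G2/M and mitosis, oxidative phosphorylation and DNA repair (medians 0.11, 0.11, 0.05 and 0.06) and dendritic cells and B lineage (−0.15 and −0.07), with adjusted p from 0.67 to 0.75 with an estimated correlation. By camera, the responses of the mature neutrophil, G2/M and oxidative phosphorylation lists also differed between the models. Without MLL-NRIP3 control arrays 1 and 2 the calls of G2/M, oxidative phosphorylation, dendritic cells and B lineage ended (0.16 to 0.83). Without 1 array the mature neutrophil call ended for MLL-NRIP3 control array 2 or 3 or deleted array 3 (0.061 to 0.41), and that of dendritic cells for MLL-AF9 control array 1 or deleted array 2 or MLL-NRIP3 deleted array 2 (0.066 to 0.12). That of oxidative phosphorylation ended for MLL-AF9 control array 3 or MLL-NRIP3 control array 2 or deleted array 1 or 2 (0.055 to 0.19), that of DNA repair for MLL-AF9 control array 2 or deleted array 2 or MLL-NRIP3 control array 3 or deleted array 1 or 2 (0.096 to 0.27), and that of B lineage for MLL-AF9 control array 1 or deleted array 2 or MLL-NRIP3 control array 1 or 2 or deleted array 1 or 2 (0.079 to 0.18). The medians of these lists also moved by over 1.5 times without 1 array, except that of dendritic cells. The mature neutrophil median was 0.25 and 0.05 without MLL-NRIP3 control arrays 1 and 3, the G2/M median 0.06 without control array 2 and the oxidative phosphorylation median 0.03 and 0.08 without deleted arrays 1 and 3 of that model. The DNA repair median was 0.04 without MLL-AF9 deleted array 2, 0.10 and 0.03 without MLL-NRIP3 control arrays 2 and 3, and 0.02, 0.01 and 0.10 without deleted arrays 1, 2 and 3 of that model. The B lineage median was −0.04 without MLL-AF9 control array 1 and −0.13 and −0.11 without MLL-NRIP3 control array 3 and deleted array 3.

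In MLL-NRIP3 leukemia single members of lists that did not pass the threshold were called. Pink1, a kinase of mitochondrial quality control, was at −1.21 ± 0.12, the DNA repair gene Xpc at −0.82 ± 0.08, Cd34 at 1.41 ± 0.21 and Hoxa5 at 1.12 ± 0.17 (log2 ± SE, limma adjusted p of 0.0019 or lower), and all 4 were also called with the model's own arrays. Sgk1, a kinase phosphorylated by mTORC2, was at 0.84 ± 0.16 (adjusted p = 0.0061) and was not called with the model's own arrays (adjusted p = 0.093).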
